A study of Homo sapiens with 6 samples.

How the data were processed

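RNA was sequenced from A375 cells, an established human melanoma line that carries an activated BRAF kinase. Cells of one group were given the solvent DMSO alone. Cells of the other group were given 1 µM BMH-21 for 24 hours. BMH-21 is a small molecule that intercalates into DNA, blocks transcription by RNA polymerase I, the enzyme that makes ribosomal RNA, and leads to loss of that enzyme's largest subunit. Each group has 3 libraries, described by the submitters as biological replicates. The sample titles mark the control libraries as time 0, while the labels' treatment protocol calls them DMSO controls, so their time in culture is not settled by the sources used here.

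Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted with a Ribo-Zero kit, and fragmented RNA was copied with random hexamers. The labels also name the molecule as polyadenylated RNA. These statements differ in how RNA without a poly(A) tail would be represented, and the levels of histone, mitochondrial and small RNA given below carry that doubt. The direct product of RNA polymerase I was depleted or not selected under either statement, so its synthesis was not measured.

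The values are TPM per gene symbol, a relative transcript abundance, deposited by the authors as one table of 25662 genes and 6 libraries. Per the submitters' processing notes, the tools were STAR, an aligner, and Salmon, which estimates transcript abundance, with the GRCh38 human genome. Their versions, settings and gene annotation are not given in the sources used here. TPM divides each gene's estimated reads by its effective length and scales every library to the same total, so a gene's TPM depends on all other genes of its library. The 6 columns summed to between 989360 and 990760, so about 1% of each library belongs to entries not used here. Salmon shares reads among similar sequences, and levels of genes with near-identical copies are uncertain for that reason.

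TPM keeps no read totals. A relative depth was estimated from genes with a mean TPM below 1, as the most frequent ratio between libraries of the TPM that a few reads are worth. Against 1 for control replicate 1, it was 1.02 and 1.16 for control replicates 2 and 3, and 1.67, 1.37 and 1.50 for BMH-21 replicates 1 to 3. By this estimate the BMH-21 libraries were the deeper ones. The TPM that a read is worth also depends on the make-up of a library, so the estimate does not measure depth alone. Absolute depth is unknown, and no counting interval is given.

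Values were analysed as log2(TPM + 1). The pseudocount of 1 shrinks the changes of genes with low TPM, so fold changes on this scale are understated for them, and ratios of mean TPM are given beside them where both levels allow. Genes with a mean TPM of at least 1 over the 6 libraries were tested, 12481 in all, and 2718 genes were at 0 in every library. BMH-21 was compared with control by limma 3.58.1 in R 4.3.3, with a linear model per gene, an empirical Bayes variance that follows the mean level, and two-sided tests with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Adjusted p-values below are from this fit unless another test is named, and ± stands for the standard deviation over the 3 libraries of a group for TPM and for the standard error for a log2 change.

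30 gene lists were fixed before the data were examined, together with the test, the alternatives and the rule for naming genes. Each list was compared with all other tested genes by limma's camera test with a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and by fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. List p-values were adjusted over the 30 lists. The rule names the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean reached 5 TPM in the higher group. It also names, for each list, the called members with the largest rise and fall and the member with the highest mean TPM, and 15 genes fixed in advance. Of these, 1 fixed gene and 1 list are not reported here, while counts over all genes, lists and named genes include them.

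The model was tested on simulated data before use, with the noise of the real libraries over 12481 genes of the comparison of BMH-21 with control. It called 14.0% of 50 genes simulated with a log2 change of 0.5, 66.0% of 50 with a change of 1, 100% of 50 with a change of 2 and 98.0% of 50 with a change of 3. Of 12281 unchanged genes 3 were called. A simulated list raised by 0.5 was called by camera with either correlation and by fry, which called 0, 0 and 1 of 29 unchanged lists in that order. Simulated genes were independent of each other, which real genes are not. The simulation also changed far fewer genes than were called in the data. Its adjustment was stricter for that reason, and its shares of called genes do not carry over directly.

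Gene positions are from GENCODE release 29 on GRCh38, to which 25551 of the 25662 symbols could be matched. The annotation used by the authors may be another release. Transcript length and GC content came from the same release. Alternatives were other pseudocounts, other filters on low values, other scalings (median-of-ratios factors, quantile normalization, leaving out abundant genes), other variance models, a term for the replicate number, and each library left out in turn. Leaving out both libraries with the number 2, and removing each library's trend with transcript length and GC content, with and without the replicate term, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.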

Results

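The data describe the transcriptome of A375 melanoma cells after 24 hours with BMH-21 at 1 µM, set against DMSO controls, with 3 libraries in each group. The comparison asks which transcripts differ after BMH-21 in these cells. Inhibition of RNA polymerase I was not measured, and its effects cannot be told apart here from those of DNA binding by the compound. Libraries of one group correlated at 0.980 to 0.992 over tested genes, and libraries of different groups at 0.934 to 0.949 (Pearson's r across genes, which are not independent). The first principal component held 70.0% of the variance and separated the groups. Between 18268 and 18767 genes were above 0 TPM in the control libraries. In the BMH-21 libraries, the deeper ones by estimate, the number was between 19326 and 19867. Deviations of BMH-21 replicates 1 to 3 from their group mean correlated with GC content at -0.29, 0.59 and -0.56 (Spearman's rho across genes). For control replicates 1 to 3 these values were 0.13, -0.26 and 0.23. In the make-up of its transcripts, control replicate 2 stood apart. Mitochondrially encoded transcripts made up 7.61% of its TPM, against 13.7% and 10.9% in control replicates 1 and 3 and between 12.4% and 14.6% in the BMH-21 libraries. Cytosolic ribosomal protein transcripts made up 33.1% of its TPM, against 25.8% and 27.6% in the other controls and between 23.5% and 26.1% in the BMH-21 libraries.

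After BMH-21, replication-dependent histone genes and the growth arrest gene CDKN1A rose, and genes of DNA replication, mitosis and double-strand break repair fell. The camera calls of these 4 lists were lost with an estimated correlation (adjusted p from 0.1002 to 0.1051). The estimate was 0.018 for the histones, close to the preset value, and ran from 0.115 to 0.346 for the other lists. The loss for the histones therefore cannot be put down to a high correlation between its genes. Despite these unlike estimates, the adjusted p hardly differed between the 4 lists. The lost calls are therefore no measure of how strongly the genes of a list are correlated. CDKN1A encodes the cyclin-dependent kinase inhibitor p21 and went from 174 ± 6.82 to 1786 ± 51.4 TPM (n = 3 each), a ratio of 10.2. RRM2, a subunit of ribonucleotide reductase, went from 142 ± 47.5 to 2.71 ± 2.29 TPM, and AURKB, a mitotic kinase, from 115 ± 7.63 to 2.46 ± 1.26 TPM. POLR1A, the largest subunit of RNA polymerase I, was at 19.5 ± 6.05 TPM in controls and 18.6 ± 2.99 TPM with BMH-21 (log2 change -0.04 ± 0.23, adjusted p = 0.912). With both number 2 libraries left out its log2 change was -0.40 (adjusted p = 0.0398). In all, 4519 of 12481 tested genes were called, 2908 higher and 1611 lower. A change of at least 2-fold on the log2(TPM + 1) scale was found in 1050 of them, 555 higher and 495 lower. The 2 groups did not overlap in 52.3% of tested genes, where chance gives 10%.

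The balance of higher and lower calls depended on scaling. Of the calls, 64.4% were higher with TPM as deposited, 44.9% with median-of-ratios scaling, 51.0% with quantile normalization and 52.1% with trends in transcript length and GC content removed. The share was 63.6% without the 50 highest genes and 68.1% without mitochondrial, ribosomal RNA, RNA polymerase III and histone genes. The median log2 change of all tested genes was 0.19 with TPM as deposited and 0.03 with median-of-ratios scaling, so log2 changes below are best read relative to 0.19. Without BMH-21 replicate 1 the count of called genes was 2796, and without BMH-21 replicate 3 it was 2885.

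**Figure D1:**
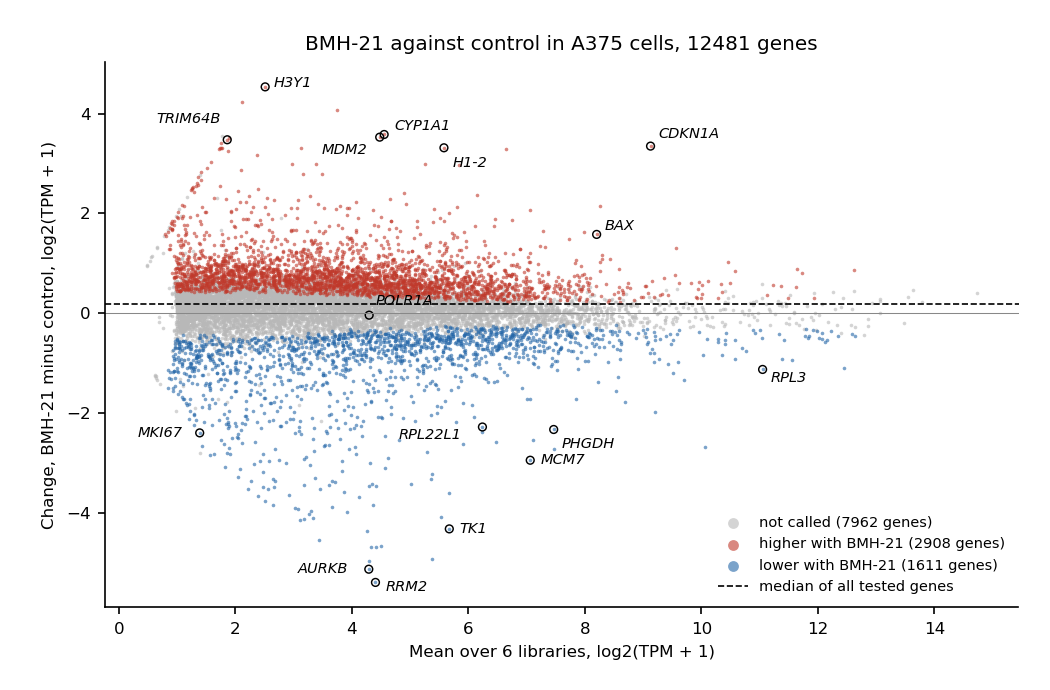
Change in log2(TPM + 1) between BMH-21 and control (vertical axis) against the mean over the 6 libraries (horizontal axis) for 12481 tested genes. Each point is a gene, coloured by its call, with 2908 higher and 1611 lower; the dashed line is the median change of 0.19, and CDKN1A stands out among highly expressed genes that rose.

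The genes with the largest rises fell into several kinds. MDM2, a ubiquitin ligase gene, went from 5.90 ± 2.42 to 75.5 ± 13.1 TPM (log2 change 3.53 ± 0.28, adjusted p = 6.23e-05). CYP1A1, a cytochrome P450 enzyme that oxidises aromatic compounds, went from 5.81 ± 0.568 to 80.4 ± 3.95 TPM, and the linker histone gene H1-2 from 14.2 ± 1.48 to 150 ± 4.54 TPM. The others include genes that were nearly silent in controls and belong to families with similar copies, so their single-gene levels are uncertain. The histone H3 variant gene H3Y1 went from 0.186 ± 0.0771 to 26.6 ± 2.88 TPM, TAF11L11 from 0.0953 ± 0.0501 to 11.5 ± 1.17 TPM, TRIM64B from 0.0894 ± 0.0469 to 11.2 ± 1.40 TPM and TRIM49D1 from 0.0348 ± 0.0602 to 9.98 ± 0.674 TPM. The pseudogene H3P21 was listed at 0 in the 3 controls and at 17.2, 14.5 and 23.0 TPM with BMH-21. H3Y1 (chromosome 5, 17654870 to 17655847), H3P21 (17625551 to 17625959) and TAF11L11 (17604177 to 17605377) are neighbours on chromosome 5, and TRIM64B (89869282 to 89876017) and TRIM49D1 (89911111 to 89921767) are neighbours on chromosome 11. The small nucleolar RNA SNORD95 was listed at 0, 34.2 and 0 TPM in controls and 43.8, 71.4 and 51.3 TPM with BMH-21 (adjusted p = 0.0325), and its call was lost without either control replicate 1 or control replicate 3 and without any single BMH-21 library (adjusted p from 0.0619 to 0.108).

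Among 30 apoptosis regulators, 11 rose and 4 fell, the same counts adjusted over the list alone (median log2 change 0.20, camera adjusted p = 0.376, fry adjusted p = 0.0115). That median lay close to the 0.19 of all tested genes, with which fry does not compare. With median-of-ratios scaling 8 rose and 4 fell, and the median was 0.02. BAX, a pore-forming activator of apoptosis, went from 170 ± 16.1 to 509 ± 5.63 TPM. BBC3, which encodes the apoptosis activator PUMA, went from 10.4 ± 1.80 to 37.5 ± 1.35 TPM. BCL2L12, a BCL2 family member, fell from 45.8 ± 3.03 to 17.7 ± 0.654 TPM. CDKN1A lies on chromosome 6 (36676460 to 36687339) and MDM2 on chromosome 12 (68808176 to 68850686). The antiproliferative gene BTG2 went from 10.3 ± 0.416 to 54.5 ± 0.363 TPM. MDM4, a relative of MDM2, was at 2.26 ± 0.14 and 2.05 ± 0.256 TPM (adjusted p = 0.603).

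Genes of cell division fell. Of 60 tested G2/M genes, 56 fell and none rose, with 58 falling adjusted over the list alone (median log2 change -2.82, camera adjusted p = 9.07e-45, adjusted p = 0.105 with an estimated correlation). Of 64 DNA replication genes, 61 fell and 1 rose, with 62 and 1 adjusted over the list alone (median -2.05, camera adjusted p = 3.46e-46, adjusted p = 0.1002 with an estimated correlation). The mitotic kinase gene PLK1 fell from 107 ± 8.06 to 3.46 ± 1.89 TPM and UBE2C, which marks mitotic regulators for destruction, from 228 ± 37.7 to 7.44 ± 5.18 TPM. The securin gene PTTG1, the G2/M member with the highest level, fell from 233 ± 40.3 to 69.8 ± 2.61 TPM. The replicative helicase subunit MCM7 fell from 370 ± 10.2 to 47.5 ± 6.08 TPM and thymidine kinase TK1 from 227 ± 18.6 to 10.8 ± 3.74 TPM. RRM2 (chromosome 2, 10120698 to 10131419) and AURKB (chromosome 17, 8204733 to 8210600) had the largest falls on the log2 scale, -5.39 ± 0.43 and -5.12 ± 0.23. The other 5 of the 10 largest falls were MYBL2, a transcription factor of cycling cells, BIRC5, which encodes survivin, the histone chaperone ASF1B, the kinetochore subunit SPC24 and the cohesin regulator CDCA5, each with a mean below 4 TPM after BMH-21. The proliferation marker MKI67 fell from 5.59 ± 3.37 to 0.147 ± 0.133 TPM. CCND1, the cyclin D1 gene, was the replication list member that rose, from 93.9 ± 21.3 to 189 ± 7.01 TPM. Of 31 DNA double-strand break repair genes, 19 fell and 1 rose, with 21 and 1 adjusted over the list alone (median -1.02, camera adjusted p = 3.07e-12, adjusted p = 0.105 with an estimated correlation). RAD54L, a recombination helicase, fell from 22.7 ± 2.88 to 0.670 ± 0.269 TPM, and RAD52, a strand-annealing protein, rose from 5.98 ± 1.44 to 10.5 ± 0.471 TPM.

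Replication-dependent histone genes moved the other way. The deposited values hold 55 members, and 18 reached the mean TPM for testing, a filter that high BMH-21 values alone can pass. Of these 18, 16 rose and none fell, and all 18 rose adjusted over the list alone (median 1.76, camera adjusted p = 6.69e-09, adjusted p = 0.1002 with an estimated correlation). Without the 50 highest genes 23 were tested, of which 19 rose and 1 fell. Across the alternatives the list median ran from 0.34 to 2.37. H2AC18, which has a near-identical copy, went from 19.4 ± 0.325 to 160 ± 32.5 TPM. The histone variant gene H2AX, which sits in the repair list, fell from 131 ± 28.5 to 49.3 ± 4.94 TPM.

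Transcripts of the ribosome and of the RNA polymerase I system moved less and in both directions. Of 79 cytosolic ribosomal protein genes, 22 fell and 1 rose, with 20 and 1 adjusted over the list alone (median -0.14, camera adjusted p = 1.18e-05, adjusted p = 0.744 with an estimated correlation). RPL3 fell from 3138 ± 225 to 1438 ± 50.2 TPM, and RPL22L1, a paralog of RPL22 that is outside this list, fell from 167 ± 31.8 to 35.3 ± 13.1 TPM. RPL22 was at 577 ± 112 and 616 ± 82.3 TPM (adjusted p = 0.629, and 0.00895 as higher with both number 2 libraries left out). RPS27, the highest member, was at 7853 ± 1358 and 9465 ± 871 TPM (adjusted p = 0.167, and 0.0198 as higher without control replicate 2). RPS6 went from 2590 ± 39.2 to 3192 ± 99.5 TPM (adjusted p = 0.0236), a call that was lost with median-of-ratios scaling, without control replicate 3 and without any single BMH-21 library (adjusted p from 0.0716 to 0.579). The ribosomal protein share was highest in control replicate 2 (33.1%) and lowest in BMH-21 replicate 2 (23.5%). Without control replicate 2 the median log2 change of cytosolic ribosomal proteins was -0.06 and the list was still called (camera adjusted p = 0.0289). With both number 2 libraries left out 25 members rose and 20 fell, the median was -0.03 and camera gave an adjusted p of 0.374, and with quantile normalization the adjusted p was 0.0566. Among 17 genes of the RNA polymerase I machinery, 2 rose and 3 fell, the same adjusted over the list alone (median -0.04, camera adjusted p = 0.261). The subunit gene POLR1H fell from 50.6 ± 2.56 to 32.4 ± 0.826 TPM, and TAF1C, part of the promoter selectivity factor, went from 23.3 ± 5.37 to 35.6 ± 3.26 TPM (adjusted p = 0.0266), a call that was lost without any single BMH-21 library (adjusted p from 0.0529 to 0.0701). CAVIN1, the highest member and also a coat protein of caveolae, was at 187 ± 10.4 and 174 ± 10.4 TPM (adjusted p = 0.349). UBTF, which opens ribosomal DNA for transcription, was at 62.9 ± 4.87 TPM in controls and 51.6 ± 4.13 TPM with BMH-21 (adjusted p = 0.0642, and 0.00771 with median-of-ratios scaling and 0.0246 without control replicate 2, as lower). Among 92 ribosome assembly factors, 10 rose and 11 fell, with 4 and 10 adjusted over the list alone (median 0.07, camera adjusted p = 0.160). With median-of-ratios scaling that median was -0.12, with 3 members higher and 24 lower and a camera adjusted p of 0.0454, and with both number 2 libraries left out 21 rose and 18 fell. TCOF1, a nucleolar cofactor of RNA polymerase I, fell from 63.7 ± 10.96 to 21.3 ± 2.61 TPM, and WDR43, a small subunit processing factor, rose from 9.96 ± 1.40 to 17.01 ± 3.09 TPM, a call lost without BMH-21 replicate 1 (adjusted p = 0.0612) or 3 (0.0590). The nucleolar proteins NPM1 (564 ± 109 and 523 ± 262 TPM) and NCL (138 ± 28.5 and 123 ± 18.1 TPM) were not called. NPM1 was at 224 TPM in BMH-21 replicate 2 and at 631 and 714 TPM in BMH-21 replicates 1 and 3, and the log2 change of NPM1 was 0.27 without BMH-21 replicate 2 (adjusted p = 0.251) against -0.26 with all libraries.

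**Figure D2:**
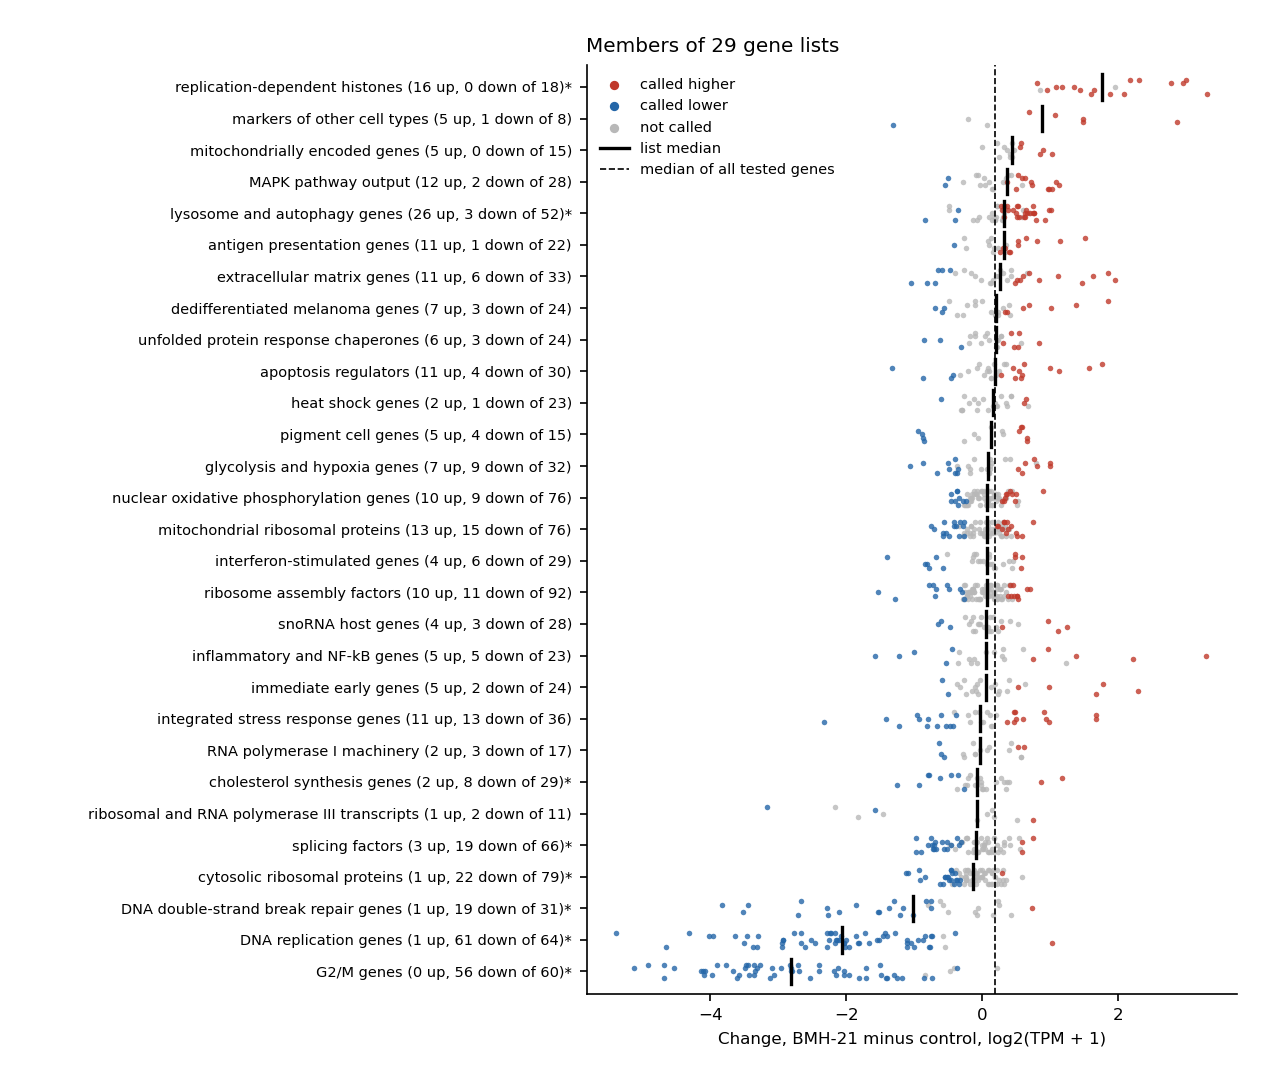
Change in log2(TPM + 1) between BMH-21 and control (horizontal axis) for the tested members of 29 lists (rows, ordered by median, with counts of members that rose and fell). Each point is a gene coloured by its call, black bars are list medians, the dashed line is the median of 0.19 for all tested genes, and a star marks lists past the camera test; G2/M genes lie lowest at -2.82 and histones highest at 1.76.

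Non-coding members of the translation system gave no list call. Of 28 snoRNA host genes, 4 rose and 3 fell, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.583). SNHG9 rose from 20.2 ± 1.91 to 49.5 ± 2.36 TPM, ZFAS1 fell from 195 ± 24.2 to 123 ± 9.64 TPM and SNHG29 was at 1801 ± 116 and 1750 ± 53.1 TPM. Of 11 ribosomal and RNA polymerase III transcripts, 1 rose and 2 fell, the same adjusted over the list alone (median -0.08, camera adjusted p = 0.348). The RNase P component RPPH1 rose from 1.29 ± 0.0637 to 2.87 ± 0.549 TPM. The signal recognition particle RNA RN7SL2 was at 81.7 ± 56.2 and 74.9 ± 6.90 TPM. RNY3 passed the test as lower (adjusted p = 0.0318) although its groups overlapped, and lost the call without control replicate 2 or 3 or BMH-21 replicate 1 or 2 (adjusted p from 0.0707 to 0.0922).

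Splicing factors and cholesterol synthesis genes passed the camera test as lower, with modest sizes. Of 66 splicing factors, 19 fell and 3 rose, the same adjusted over the list alone (median -0.08, camera adjusted p = 0.000347, adjusted p = 0.506 with an estimated correlation). The Sm protein genes SNRPB and SNRPD2 fell from 817 ± 20.1 to 416 ± 10.8 TPM and from 1507 ± 196 to 1044 ± 33.0 TPM, and SRSF5 rose from 63.7 ± 5.20 to 107 ± 0.767 TPM. Of 29 cholesterol synthesis genes, 8 fell and 2 rose, with 8 and 3 adjusted over the list alone (median -0.08, camera adjusted p = 0.0191, adjusted p = 0.506 with an estimated correlation). The sterol isomerase EBP fell from 107 ± 3.34 to 44.1 ± 0.623 TPM and FDPS from 245 ± 19.5 to 141 ± 0.959 TPM, while the sterol reductase TM7SF2 rose from 16.01 ± 2.82 to 37.3 ± 1.37 TPM. The fry test called neither list nor the cytosolic ribosomal proteins.

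Lysosome and autophagy genes passed as higher. Of 52 members, 26 rose and 3 fell, with 29 and 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.00354, adjusted p = 0.744 with an estimated correlation). BECN1, which starts autophagosome formation, rose from 48.0 ± 6.50 to 97.99 ± 7.68 TPM, the lysosomal protein gene PSAP from 637 ± 80.2 to 974 ± 68.4 TPM, and the enzyme GLA fell from 30.7 ± 0.932 to 16.7 ± 0.681 TPM. With median-of-ratios scaling 17 members rose and 4 fell. In total 9 lists passed the camera test with the preset correlation, and none passed with an estimated correlation, where 5 lists had an unadjusted p under 0.05. The fry test called 9, of which 6 had passed camera and 3 had not, namely the antigen presentation genes, the apoptosis regulators and the markers of other cell types.

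Stress and metabolic lists were split. Of 36 integrated stress response genes, 11 rose and 13 fell, the same adjusted over the list alone (median -0.03, camera adjusted p = 0.0846). Without control replicate 3 or BMH-21 replicate 2 the list passed as lower (adjusted p = 0.0431 and 0.0420). ATF3, a stress-induced transcription factor, rose from 3.60 ± 1.39 to 13.3 ± 0.226 TPM, while the serine synthesis enzyme PHGDH fell from 396 ± 45.9 to 78.1 ± 5.45 TPM and the serine-using mitochondrial enzyme SHMT2 from 369 ± 38.5 to 189 ± 4.42 TPM. Of 24 unfolded protein response chaperones, 6 rose and 3 fell, the same adjusted over the list alone (median 0.21, camera adjusted p = 0.977). The balance reversed with median-of-ratios scaling (2 rose, 6 fell) and with length and GC trends removed (2 rose, 5 fell). The ubiquitin ligase SYVN1 rose from 52.97 ± 7.89 to 95.1 ± 10.1 TPM, SDF2L1 fell from 38.0 ± 3.15 to 20.6 ± 1.07 TPM, and CALR, at 879 ± 23.5 and 1086 ± 40.4 TPM, was called higher but not with median-of-ratios scaling or without any single BMH-21 library (adjusted p from 0.0604 to 0.466). Of 23 heat shock genes, 2 rose and 1 fell, with 1 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.828). FKBP4 fell from 147 ± 8.41 to 95.9 ± 4.44 TPM, HSPB8 went from 5.12 ± 1.51 to 8.41 ± 0.879 TPM with a call that was lost with median-of-ratios scaling, quantile normalization and without any single library except control replicate 3 (adjusted p from 0.0609 to 0.0904), and HSPA8 was at 1267 ± 147 and 1477 ± 77.7 TPM. Of 32 glycolysis and hypoxia genes, 7 rose and 9 fell, with 8 and 9 adjusted over the list alone (median 0.09, camera adjusted p = 0.261). The lactate transporter SLC16A3 rose from 15.3 ± 3.41 to 31.2 ± 2.98 TPM, ALDOC fell from 57.9 ± 3.82 to 27.3 ± 2.27 TPM, and GAPDH was at 12276 ± 1376 and 10765 ± 171 TPM (adjusted p = 0.250). ACTB was at 2023 ± 379 and 2013 ± 173 TPM.

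Of 15 mitochondrially encoded genes, 5 rose and none fell, the same adjusted over the list alone (median 0.43, camera adjusted p = 0.112), and 1 rose with median-of-ratios scaling. Without control replicate 1 the list passed as higher (adjusted p = 0.00404), and with both number 2 libraries left out its median was 0.12. MT-ND1 went from 1037 ± 407 to 2017 ± 250 TPM (adjusted p = 0.0160), a call that was lost without control replicate 3 (adjusted p = 0.0511), and MT-ATP8 was at 25292 ± 10930 and 31613 ± 3955 TPM. Both were lowest in control replicate 2, whose mitochondrial share was 7.61%. Of 76 nuclear oxidative phosphorylation genes, 10 rose and 9 fell, with 10 and 8 adjusted over the list alone (median 0.08, camera adjusted p = 0.355, and 0.0281 as lower without control replicate 1). With median-of-ratios scaling 1 rose and 13 fell, with length and GC trends removed 5 rose and 14 fell, and with both number 2 libraries left out 32 rose and 8 fell. ATP5F1E rose from 284 ± 57.4 to 530 ± 113 TPM, ATP5MC2 fell from 794 ± 79.7 to 574 ± 8.65 TPM and COX7C was at 1322 ± 278 and 1510 ± 184 TPM (adjusted p = 0.337, and 0.0396 as higher without control replicate 2). Of 76 mitochondrial ribosomal proteins, 13 rose and 15 fell, with 14 and 15 adjusted over the list alone (median 0.08, camera adjusted p = 0.172, and 0.0225 and 0.0400 as lower without control replicate 1 or 3). These counts were 1 and 20 with median-of-ratios scaling, 3 and 18 with length and GC trends removed, and 27 and 14 with both number 2 libraries left out. MRPL12 fell from 181 ± 20.7 to 107 ± 3.68 TPM, MRPL28 was at 258 ± 39.8 and 301 ± 8.25 TPM, and MRPS33, at 63.7 ± 13.5 and 108 ± 14.7 TPM, was called higher except with median-of-ratios scaling.

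Lists tied to the melanoma cell state showed mixed changes. Of 28 genes of MAPK pathway output, 12 rose and 2 fell, with 14 and 2 adjusted over the list alone (median 0.37, camera adjusted p = 0.0895, and 0.0213 and 0.0466 as higher without control replicate 1 or BMH-21 replicate 3). The phosphatase gene DUSP4 rose from 58.6 ± 8.31 to 129 ± 2.33 TPM, and the matrix protein gene TNC was at 437 ± 110 and 352 ± 40.8 TPM (adjusted p = 0.256, and 0.0132 as lower without control replicate 2). LZTS1 fell from 5.56 ± 0.781 to 3.50 ± 0.412 TPM (adjusted p = 0.0314) and MYC from 12.5 ± 2.88 to 8.38 ± 0.188 TPM (adjusted p = 0.0485). Both calls were lost without either of control replicates 1 and 3 and without either of BMH-21 replicates 1 and 3, and that of MYC also without BMH-21 replicate 2 (adjusted p from 0.0760 to 0.130). Of 15 pigment cell genes, 5 rose and 4 fell, the same adjusted over the list alone (median 0.13, camera adjusted p = 0.585). RAB38 rose from 27.8 ± 1.29 to 44.9 ± 4.26 TPM, the endothelin receptor EDNRB fell from 22.0 ± 1.88 to 10.97 ± 0.378 TPM, and the lineage factors SOX10 (540 ± 126 and 654 ± 52.4 TPM) and MITF (1.42 ± 0.423 and 1.29 ± 0.0211 TPM) were not called. Of 24 dedifferentiated melanoma genes, 7 rose and 3 fell, the same adjusted over the list alone (median 0.21, camera adjusted p = 0.908). The balance reversed with median-of-ratios scaling (3 rose, 7 fell) and with both number 2 libraries left out (4 rose, 7 fell). THBS1 rose from 25.1 ± 7.56 to 90.2 ± 0.765 TPM, the intermediate filament gene VIM fell from 2111 ± 193 to 1303 ± 85.8 TPM, and SERPINE2, at 1986 ± 252 and 2553 ± 102 TPM, was called higher but not with median-of-ratios scaling, without control replicate 3 or without any single BMH-21 library (adjusted p from 0.0848 to 0.318). Of 33 extracellular matrix genes, 11 rose and 6 fell, the same adjusted over the list alone (median 0.27, camera adjusted p = 0.760). With median-of-ratios scaling 8 rose and 8 fell, and with both number 2 libraries left out 11 rose and 10 fell (median 0.08). The collagen gene COL16A1 rose from 6.95 ± 2.39 to 28.9 ± 1.55 TPM, FBLN1 fell from 8.22 ± 2.39 to 3.36 ± 0.293 TPM, and SPARC, at 2171 ± 117 and 3192 ± 111 TPM, was called higher except with median-of-ratios scaling. Of 24 immediate early genes, 5 rose and 2 fell, with 5 and none adjusted over the list alone (median 0.05, camera adjusted p = 0.864). DUSP2 was at 4.25 ± 0.885 and 2.49 ± 0.584 TPM (adjusted p = 0.0485, a call that was lost without control replicate 1 or 3 or BMH-21 replicate 1 or 3, with adjusted p from 0.102 to 0.169), and IER2 at 120 ± 12.4 and 112 ± 8.78 TPM.

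Immune-related lists gave no camera call either. Of 22 antigen presentation genes, 11 rose and 1 fell, with 11 and 3 adjusted over the list alone (median 0.32, camera adjusted p = 0.0846, and 0.0329 as higher without control replicate 2, fry adjusted p = 0.000798), and 3 rose and 3 fell with median-of-ratios scaling. CIITA, the activator of class II rather than class I genes, rose from 31.0 ± 5.19 to 89.5 ± 6.04 TPM and the class II invariant chain CD74 from 2603 ± 486 to 4527 ± 400 TPM. PSMB9, a proteasome subunit of the class I pathway, fell from 35.6 ± 4.33 to 26.2 ± 1.14 TPM (adjusted p = 0.0251), a call that was lost without any single BMH-21 library and without control replicate 3 (adjusted p from 0.0673 to 0.0774). Of 29 interferon-stimulated genes, 4 rose and 6 fell, the same adjusted over the list alone (median 0.07, camera adjusted p = 0.261), and 1 rose and 7 fell with median-of-ratios scaling (median -0.11). IRF9 rose from 10.2 ± 0.206 to 15.9 ± 0.592 TPM, IFITM1 fell from 29.9 ± 3.33 to 10.7 ± 0.360 TPM and IFITM3 was at 792 ± 104 and 904 ± 44.1 TPM. Of 23 inflammatory and NF-kB genes, 5 rose and 5 fell, with 6 and 5 adjusted over the list alone (median 0.05, camera adjusted p = 0.828). The cytokine gene IL24 rose from 31.0 ± 2.69 to 313 ± 9.58 TPM, a ratio of 10.1, and the adaptor gene TRAF1 fell from 32.3 ± 3.20 to 10.2 ± 0.714 TPM.

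Of 25 markers of other cell types, 8 were tested, of which 5 rose and 1 fell, the same adjusted over the list alone (median 0.88, camera adjusted p = 0.186, fry adjusted p = 0.000187). The fibroblast marker DCN went from 0.597 ± 0.263 to 10.6 ± 1.37 TPM and the keratin gene KRT10 from 25.4 ± 3.06 to 41.7 ± 1.83 TPM, while the macrophage and lysosome marker CD68 fell from 36.8 ± 1.22 to 14.2 ± 1.35 TPM. DCN, HBA1 (means of 0.269 and 2.51 TPM) and KDR (0.360 and 1.85 TPM) reached the mean TPM for testing only through their BMH-21 values. The filter thus favoured rises, and the counts, the median and the fry result carry that limit.

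The median of 10 lists changed sign with median-of-ratios scaling, and none of these 10 passed the camera test. With that scaling more members fell than rose among the snoRNA host genes (6 and 3), the heat shock genes (3 and 1) and the pigment cell genes (5 and 4). With both number 2 libraries left out 8 immediate early genes fell and 5 rose. The camera test compares a list with all other tested genes, not with 0. For the ribosome assembly, snoRNA host, nuclear oxidative phosphorylation, mitochondrial ribosomal protein, dedifferentiated melanoma, glycolysis, heat shock and inflammatory lists the median and mean were positive while the test pointed down. The pigment cell and interferon lists had a positive median (0.13 and 0.07), a negative mean (-0.01 and -0.05) and a test that pointed down. The RNA polymerase I machinery had a negative median (-0.04), a positive mean (0.03) and a test that pointed down.

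**Figure D3:**
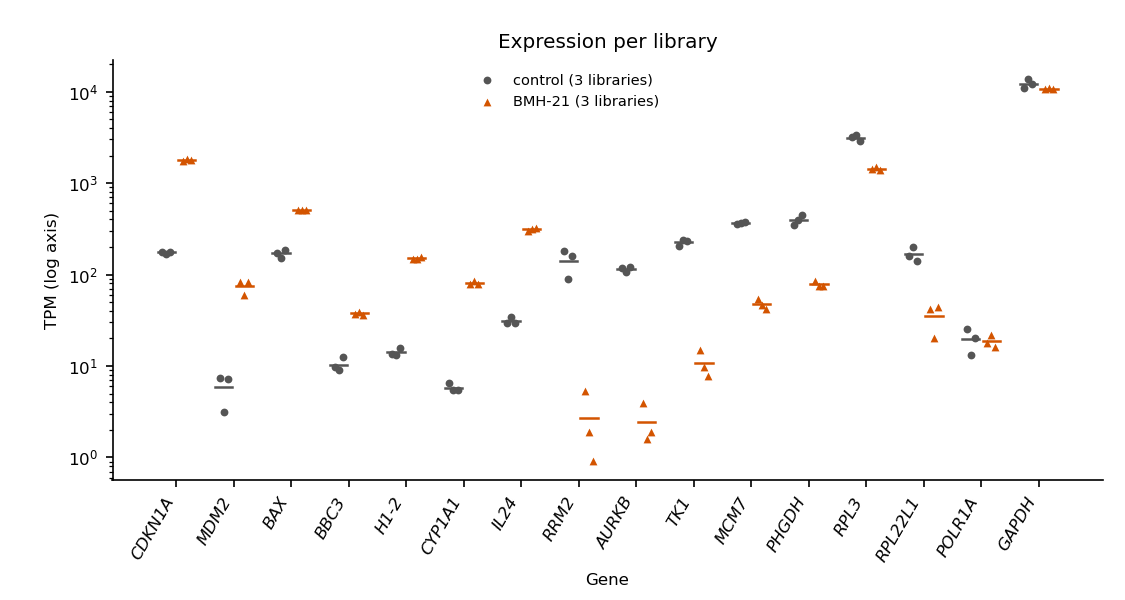
TPM (vertical log axis) per library for 16 named genes (horizontal axis), with control libraries as grey circles, BMH-21 libraries as orange triangles and horizontal bars for the mean of 3 libraries. CDKN1A lies at a mean of 174 TPM in controls and 1786 TPM with BMH-21, RRM2 at 142 and 2.71 TPM, and POLR1A at 19.5 and 18.6 TPM.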

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

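The alternatives that left out both number 2 libraries, or removed length and GC trends, were chosen after seeing the data; the others were fixed before. TPM keeps no read totals, so the noise of low genes cannot be set against their depth. With 3 libraries a group most simulated log2 changes of 0.5 stayed uncalled, in a simulation with far fewer changed genes than the data.

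Leaving out 1 library at a time, the genes changed by BMH-21 (4519) ranged from 2796 to 4809, the genes higher with BMH-21 (2908) from 1671 to 2838, the genes lower with BMH-21 (1611) from 1125 to 1991, the genes changed by BMH-21 at least 2-fold (1050) from 1021 to 1188 and the gene lists shifted by BMH-21 (9) from 9 to 13. With sample weights 7851 genes were called, 4992 higher and 2859 lower; the weights did not fully converge. Median-of-ratios scaling left 1928 genes higher, and removal of length and GC trends called 2447 lower. At least 2-fold, a pseudocount of 5 left 489 genes, which its shrinkage of low genes explains, and a mean TPM of at least 5 left 697, with fewer genes tested. With an estimated correlation 0 lists passed camera. For the weights, the scaling and the trends the cause was not tested. No called gene or list named in the report reversed.

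Of 90 called named genes, 75 kept their call and direction in every alternative that tested them. Across named genes and alternatives, 98 calls were lost and 32 gained, and 9 uncalled genes changed sign in 28 cases. Among lists 14 calls were lost and 29 gained. Leaving out both number 2 libraries gave 5845 called genes, 4132 of them called with all libraries. The robust variance model has no list test.

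The replicate numbers did not pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.04, -0.34 and -0.08, while control replicate 2 and BMH-21 replicate 3 correlated at 0.33. With a replicate block 3223 genes were called, and with length and GC trends removed under the same block 4052.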

Other observations

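The tests of early-embryo genes, histones and aryl hydrocarbon receptor targets below were chosen after their values were seen. The correction behind the test of length and GC content was also added after the data were seen.

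Several of the largest rises belong to genes otherwise active in the early embryo. A list of 41 such genes, most of them known targets of the embryonic transcription factor DUX4, was written after the rises were seen, so its direction is not independent evidence. Of its 20 tested members 19 rose and none fell, and 35 of the 41 were higher in every BMH-21 library than in every control. Most tested members were near 0 in controls and passed the mean TPM for testing only through their BMH-21 values. Such members could not have been called lower, so the count of rises among tested members is no evidence of direction. Their summed TPM went from 7.95 ± 1.03 to 134 ± 18.2 (n = 3 each), a ratio of 16.9. ZSCAN4, a single-copy gene of this programme, was listed at 0 in the 3 controls and averaged 1.41 ± 0.4999 TPM with BMH-21, KHDC1L went from 0.101 ± 0.174 to 3.10 ± 0.310 TPM, PRAMEF12 from 0.0423 ± 0.0135 to 6.88 ± 0.400 TPM and MBD3L2 from 0.194 ± 0.222 to 10.3 ± 1.13 TPM. Such a move was uncommon. Of 11981 genes with a control mean below 0.5 TPM, 222 (1.85%) reached a mean of at least 1 TPM with groups that did not overlap, and 26 of the 39 listed genes in that range did so.

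Greater depth of the BMH-21 libraries cannot account for the early-embryo rise. The lowest BMH-21 sum was 14.01 times the highest control sum, while the largest estimated ratio of depths was 1.67. Sharing of reads among the listed copies would leave their sum alone, but it rose by a ratio of 16.9. Reads drawn from copies outside the list stay open in part. Of 10 members without such a copy, 8 were higher in every BMH-21 library than in every control, and the other 2, DUXA and RFPL4B, were above 0 in 1 BMH-21 library and in no control. Among the 8, ZSCAN4, KHDC1L and CCNA1 averaged above 1 TPM with BMH-21. The means of ZNF280A, TPRX1, LEUTX, SLC34A2 and KDM4E lay near the floor, from 0.0899 to 0.831 TPM. DUX4 itself was not analysed here, and nothing here links the rise to inhibition of RNA polymerase I rather than to DNA binding by BMH-21.

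CYP1A1 is the classic target of the aryl hydrocarbon receptor, a sensor of flat aromatic molecules. Of 8 other tested targets on a list written after its rise was seen, 6 rose and none fell. With CYP1A1 the list holds 15 genes, of which 8 were higher in every BMH-21 library than in every control. Its untested members, among them CYP1A2, UGT1A6, XDH and EREG, were low in both groups, and their groups overlapped. CYP1B1 reached the mean TPM for testing only through its BMH-21 values. TIPARP went from 11.1 ± 1.99 to 39.3 ± 6.95 TPM, the receptor's repressor AHRR from 10.5 ± 2.72 to 27.8 ± 2.003 TPM and CYP1B1 from 0.343 ± 0.274 to 2.61 ± 0.308 TPM. BMH-21, a planar compound, may activate this receptor directly. Some of the targets that rose, SLC7A5 and STC2, also sit in the integrated stress response list, and whether the receptor is needed was not tested.

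The replication-dependent histones rose while cell-cycle genes fell. More cells in S phase should raise both, but the DNA replication genes had a median log2 change of -2.05. The share of cells in S phase was not measured, and these transcripts are only an indirect sign of it. More RNA without a poly(A) tail in the BMH-21 libraries should raise ribosomal and RNA polymerase III transcripts by about the histone median of 1.76. Their median was -0.0800 with a standard deviation of 1.30. This cannot decide the question, because ribosomal RNA is made by the polymerase that BMH-21 blocks and was depleted or not selected. Small RNAs were also uneven, with RN7SL2 at 81.7 ± 56.2 TPM in controls. Sharing of reads among the listed copies would leave their sum alone, but summed histone TPM went from 97.1 ± 6.62 to 583 ± 45.9, a ratio of 6.01. Reads drawn from copies outside the list stay open, since the near-identical copy of H2AC18 is not on it. Polyadenylated histone transcripts, which cells leaving the cycle are known to make, may be behind the rise, and this was not tested.

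More genes were called higher than lower (64.4% of calls). The scaling of TPM could produce this, since with median-of-ratios scaling 44.9% of calls were higher and the median log2 change went from 0.19 to 0.03. With length and GC trends removed 52.1% of calls were higher, but that also moved the median to 0.05. Quantile normalization, which has no length or GC term, gave 51.0% and a median of 0.06. A role of length and GC content therefore cannot be told apart from the shift of the median. Detection of more low genes in the deeper BMH-21 libraries could not, since among genes with a mean TPM of at least 5 the share was 63.0%. Without the 50 highest genes the share was 63.6%. Whether most transcripts rose in absolute amount was not tested, as TPM holds no absolute amounts.

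The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 4519 genes and the highest other split 1, so 1 of 10 splits gave as many. For changes of at least 2-fold the real split gave 1050 and the highest other 1, again 1 of 10. For gene lists, 9 of 10 splits called at least the 9 lists of the real one, and the highest other called 17. Every other split mixes controls and BMH-21 libraries unevenly, so part of the treatment difference stays in it. The median of the DNA replication genes lay 2.24 from that of all tested genes in the real split, and up to 0.83 in another. The other splits are therefore no chance reference for genes or lists. Whether the number of lists past the camera test with a preset correlation exceeds chance cannot be decided from them. Of the 9 called lists, 6 had their lowest camera p in the real split (among them G2/M, DNA replication, histones, double-strand break repair and cholesterol synthesis), and 3 did not (cytosolic ribosomal proteins, splicing factors, lysosome and autophagy).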
